A study of Cucumis sativus with 12 samples.

How the data were processed

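RNA was measured in 12 libraries of cucumber stigma and style at anthesis, 3 of each of 4 genotypes. Per the submitters' processing notes, HISAT2, HISAT and DESeq2 were used; their versions, the genome build and the annotation are not given in the sources used here. The series table, as deposited by the authors, gives read counts and FPKM values for 24345 genes, 1097 of them new gene models, with fold changes and FDR values of the authors' own DESeq2 comparisons and protein and pathway annotation. Count columns hold whole numbers, per the file headers and the deposited values. FPKM values are normalized by the authors to gene length and library size, per the file headers. The authors' log2 fold changes and FDR values were used only to describe the authors' deposited table. Columns headed DM were read as the double mutant.

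Library totals were about 32155600 to 37986900 counts. Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with its minimum count of 10, TMM factors, and glmQLFit and glmQLFTest on all 4 groups in 1 fit with no block, with Benjamini-Hochberg adjustment per contrast and a threshold of 0.05. The design written before the data were examined assumed FPKM and named this test for the case that counts were given. Standard errors are the fold change divided by the root of F. Gene lists, 32 fixed before the data were examined as patterns on the Swiss-Prot description or else the non-redundant protein name, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, where at least 5 members were tested. Another 4 lists (morning and evening clock genes, xylem and phloem markers) were added after the data were seen. The list of targeted genes held only the 2 genes named SPATULA and was not tested. GO and KEGG terms of 10 to 500 members were tested with a one-sided Fisher exact test against all tested genes with a term of that kind.

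Genes are named by a rule fixed before the data were examined: for each mutant against WT the 10 largest rises and 10 largest falls among called genes whose libraries did not overlap, with a mean of at least 2 FPKM in the higher group and an informative protein name; 5 in each direction for the other contrasts; up to 4 called members per list in the double mutant; and the genes named SPATULA. Chance gives no overlap of 3 against 3 libraries in 10% of genes. None of the IDs matched the RefSeq table, so names come from the deposited annotation, and no coordinates are given. Replicate pairs all differed by more than sampling noise (chi-square per degree of freedom of at least 14.1), so none was merged.

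On simulated counts for the double mutant against WT, with 50 changed genes per fold size among 18652 genes, edgeR recovered 22% of 2-fold, 76% of 4-fold and 94% of 8-fold changes with 12 libraries. Without Csalc replicate 3 it recovered 66%, 98% and 100% among 18816 genes. Among the simulated calls with 12 libraries, 3 of 100 by edgeR and 61 of 178 by DESeq2 1.42.0 were unchanged genes. These were 9 of 155 and 38 of 207 without Csalc replicate 3. Every simulated library was drawn at the spread of the whole fit, which with 12 libraries includes that of Csalc replicate 3. The rates hold for that setting only. Alternatives covered limma on log2(FPKM + 1) with other pseudocounts, filters, scalings and weights, fits of the compared groups, a replicate block, DESeq2 and each library left out. Intervals and floors cover counting error only.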

Results

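Messenger RNA was sequenced from cucumber stigma and style at anthesis, the opening of the flower. The 12 libraries fell into 4 genotypes with 3 biological replicates each: wild type (WT), a mutant of SPATULA (Csspt), a mutant of ALCATRAZ (Csalc) and the double mutant (Csspt Csalc). SPATULA and ALCATRAZ are related bHLH transcription factors with known roles in carpel development, and the series asks how their loss affects the transmitting tract, the tissue that pollen tubes cross. The libraries held about 32155600 to 37986900 counts each, and 18850 genes passed the filter on low counts.

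SPATULA was the protein name of 2 genes, and no gene carried the name ALCATRAZ, so which gene was mutated in which line is not assigned here. Csa2G356640 had mean FPKM values (± SD, n = 3) of 20.2 ± 0.699 in WT, 19.9 ± 0.997 in Csspt, 9.97 ± 3.56 in Csalc, where replicate 3 had 5.87, and 11.2 ± 2.48 in the double mutant. Its log2 fold change against WT was -0.09 ± 0.31, adjusted p = 0.981 in Csspt, -1.11 ± 0.31, adjusted p = 0.135 in Csalc and -0.97 ± 0.31, adjusted p = 0.0887 in the double mutant, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without Csalc replicate 3, the same test gave -0.78 ± 0.15, adjusted p = 0.0176 in Csalc and -0.97 ± 0.13, adjusted p = 4.46e-04 in the double mutant. Csa6G491000 lay near the detection floor, at 0.153, 0.0664, 0.131 FPKM in WT and 0.250, 0.322, 0.226 FPKM in the double mutant. A mutation need not lower its transcript, so these values do not check the genotype labels.

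Csalc replicate 3 stood apart from every other library. Its log2 CPM correlated with the others at 0.810 to 0.856, whereas the other 11 libraries correlated at 0.974 to 0.985 within groups and 0.927 to 0.975 between groups. LHY (Csa6G095910), a morning gene of the circadian clock, had 1616 and 1478 CPM in Csalc replicates 1 and 2 and 5.97 CPM in replicate 3. (3S,6E)-nerolidol synthase (Csa1G066550), a terpene synthase, had 3802, 3299 and 1.13 CPM in the same libraries. All groups share one estimate of the spread, and the common biological coefficient of variation was 0.363 with this library and 0.193 without it. More genes were called in every contrast without it. In contrasts that include Csalc, its omission changes the group mean as well as the spread. Counts of called genes without it are given beside those with it. So are called list members in the double mutant against WT, and terms in Csalc and the double mutant against WT. This choice was made after the data were seen.

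**Figure D1:**
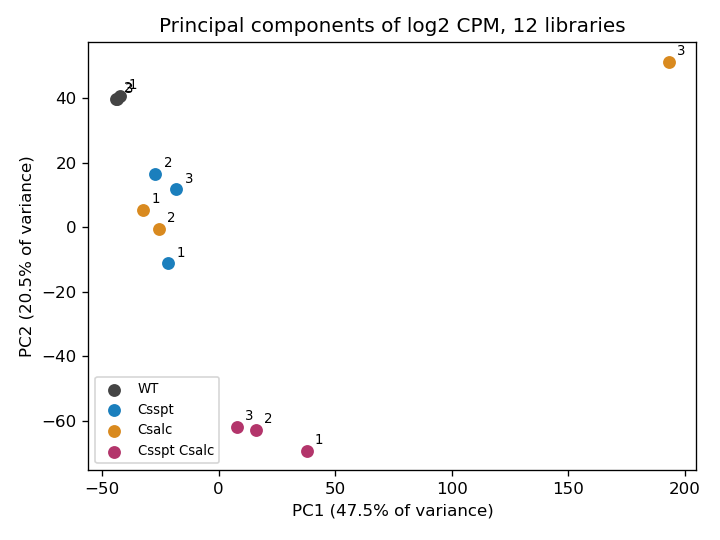
Principal components of log2 CPM for the 12 libraries, numbered by replicate; the axes give PC1 and PC2 in component units with their share of variance (47.5% and 20.5%). Csalc replicate 3 sits at 193 on PC1, and the double mutant libraries sit at 7.97 to 37.7.

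In Csspt, a WIP zinc finger factor, an expansin and pectin enzymes were among the 10 genes that fell against WT, although the wall-loosening and pectin lists were not called (medians 0.16 and -0.06, camera adjusted p = 0.521 and 0.0561). WIP2 (Csa3G810580), named for a zinc finger protein needed for transmitting tract development in Arabidopsis, went from 46.0 ± 0.254 CPM in WT to 12.4 ± 0.863 in Csspt (SD, n = 3; log2 fold change -1.89 ± 0.23, adjusted p = 0.0319). Expansin-A11 (Csa2G346000), a wall-loosening protein, went from 626 ± 38.7 to 187 ± 5.74 CPM, and rhamnogalacturonate lyase B (Csa3G892760), a pectin-cleaving enzyme, from 248 ± 5.58 to 65.3 ± 24.7. Pectinesterase 67 (Csa3G166360) had a log2 fold change of -1.45 ± 0.13, adjusted p = 0.00657, and the cutin-related cytochrome P450 77A3 (Csa6G044530) of -1.13 ± 0.12, adjusted p = 0.0126. UPSTREAM OF FLC (Csa4G027920) and transmembrane protein 87B (Csa4G377710) fell to log2 fold changes of -1.47 ± 0.20 and -0.86 ± 0.12. A pair of genes with the same pentatricopeptide repeat name, Csa3G810570 and Csa3G810560, were also lower, at -1.95 ± 0.18 and -1.74 ± 0.25. Reads may be shared between such copies, which was not measured, so their separate values are uncertain. The IDs of this pair and of WIP2 (Csa3G810580) run in sequence, and whether their falls are separate was not tested. BEL1-like homeodomain protein 8 (Csa1G118890) was the only named riser, at 1.16 ± 0.16, adjusted p = 0.0481.

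In this comparison 1 gene rose and 10 fell among 18850 tested (edgeR, adjusted p under 0.05), while without Csalc replicate 3, 379 rose and 521 fell among 19060. The auxin list was lower (median log2 fold change -0.38 over 115 genes; camera adjusted p = 7.08e-06), with 0 members called up and 0 down with 12 libraries, and adjusted p = 0.228 with an estimated correlation. An uncalled member can still differ. PIN2 (Csa1G427480) had 24.3, 27.1 and 19.9 CPM in WT and 4.99, 4.60 and 6.47 in Csspt. Ribosomal protein genes were higher by a median of 0.13 (camera adjusted p = 0.00591), and adjusted p = 0.990 with an estimated correlation. No gene was called without WT replicate 3, Csspt replicate 2 or Csspt replicate 3, where edgeR gave 0 calls. With all 12 libraries, 1415 genes had an unadjusted edgeR p under 0.05, where chance alone would give 942.5, and DESeq2 called 321.

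In Csalc, a GDSL lipase and a NAC factor were among the largest falls, and ABC transporter G32 and CER3 among the rises, although the cuticle and surface lipid list was not called (2 up and 4 down of 107, camera adjusted p = 0.417). GDSL esterase/lipase (Csa6G518310) went from 74.1 ± 6.86 CPM in WT to 3.11 ± 1.83 in Csalc (log2 fold change -4.58 ± 0.38, adjusted p = 0.00118). NAC transcription factor 56 (Csa3G100800) fell from 159.8 ± 8.54 to 21.9 ± 13.6 CPM, and the auxin efflux carrier PIN2 (Csa1G427480) from 23.8 ± 3.65 to 3.69 ± 2.68, a log2 fold change of -2.68 ± 0.51, or -3.48 ± 0.37 without Csalc replicate 3. U-box domain-containing protein 51 (Csa6G363600) and aldehyde dehydrogenase 3F1 (Csa4G291370) had log2 fold changes of -2.76 ± 0.20, adjusted p = 7.50e-04 and -2.85 ± 0.25, adjusted p = 0.00152. Epoxide hydrolase 3 (Csa2G247580), heparanase-like protein 2 (Csa3G165650), carboxylesterase 9 (Csa6G076740) and UPSTREAM OF FLC (Csa4G027920) fell to -3.35 ± 0.62, -2.93 ± 0.41, -2.87 ± 0.37 and -2.79 ± 0.21. The oxime monooxygenase CYP71AN24 (Cucumis_sativus_newGene_1864) had a log2 fold change of -2.82 ± 0.54, adjusted p = 0.0470. Leaving out a single library moved some folds by over 1.5 times, to log2 values of -5.17 ± 0.25 for the GDSL lipase without Csalc replicate 1, -3.63 ± 0.30 for heparanase-like protein 2 without Csalc replicate 2 and -3.51 ± 0.53 for CYP71AN24 without Csalc replicate 1.

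Among the rises in Csalc, ABC transporter G32 (Csa2G005890), a cutin transporter in Arabidopsis, went from 14.2 ± 0.780 to 108 ± 24.6 CPM (log2 fold change 2.93 ± 0.27, adjusted p = 0.00166). CER3 (Csa1G294020), a wax synthesis enzyme, went from 32.6 ± 2.16 to 141 ± 29.6 CPM. A repetitive proline-rich wall protein (Csa5G623650), an inactive receptor kinase (Csa6G133750) and GRAVITROPIC IN THE LIGHT 1 (Csa6G188040) had log2 fold changes of 3.15 ± 0.59, 2.48 ± 0.43 and 2.35 ± 0.41. The first of these had 2.25 ± 0.41 without Csalc replicate 3. Pectinesterase 51 (Csa2G302140), dirigent protein 20 (Csa4G280630), 7-dehydrocholesterol reductase (Csa7G447780), peptide methionine sulfoxide reductase (Csa1G002810) and phenylacetaldehyde reductase (Csa6G439420) rose by 1.93 ± 0.36, 1.86 ± 0.31, 1.77 ± 0.31, 1.76 ± 0.31 and 1.66 ± 0.31 on the log2 scale.

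In this comparison 30 genes rose and 118 fell among 18850 tested (edgeR, adjusted p under 0.05), while without Csalc replicate 3, 342 rose and 489 fell among 19060. Ribosomal protein genes were higher (median log2 fold change 0.43, camera adjusted p = 1.09e-17), as were cell cycle genes (median 0.46, camera adjusted p = 0.00921), while auxin genes were lower (median -0.15, camera adjusted p = 0.00124); each of the 3 had adjusted p = 0.735 with an estimated correlation. In Csalc replicate 3 alone, ribosomal protein genes differed from replicates 1 and 2 by a median of 0.65 and cell cycle genes by 0.76 on the log2 scale. Leaving out Csalc replicate 3 ended the camera call (adjusted p then in brackets) of cell cycle genes (0.132). Its omission brought under the threshold photosynthesis genes (2.10e-07, upward, or 0.495 with an estimated correlation), defence proteins (0.00774, upward, or 0.0814 with an estimated correlation) and phenylpropanoid genes (0.00247, upward, or 0.368 with an estimated correlation). With all 12 libraries, camera gave photosynthesis genes a downward direction beside a median of 0.21. No GO or KEGG term passed in the 12-library calls, while without Csalc replicate 3 GO passed for 1 rising and 1 falling term and KEGG for 3 and 1. The count was 1271 without Csalc replicate 1 and 33 without WT replicate 3.

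In the double mutant, 9-lipoxygenase, copper transporter, glucanase and sieve element genes were among the largest rises. Genes already lower in Csalc, some of them lower in Csspt too, were among the largest falls. Linoleate 9S-lipoxygenase A (Csa2G023910) had 0 counts in WT and 1906 in the double mutant, at least 548-fold higher over the group floor of 3 counts. Lipoxygenases Csa2G023920 and Csa2G023900 went from 0.292 ± 0.0590 to 27.2 ± 5.87 and from 1.08 ± 0.300 to 68.8 ± 15.0 CPM, and lipoxygenase Csa2G028480 rose by 5.58 ± 1.35 on the log2 scale. Lipoxygenase Csa2G028500 had 4 counts in WT, all in replicate 3, and 237 in the double mutant, and was called with and without that library (adjusted p = 0.0231 and 0.0402). Reads may be shared among these related genes, which was not measured, so their separate values are uncertain. SIEVE ELEMENT OCCLUSION B genes, for phloem proteins, rose by 6.69 ± 1.30 (Csa2G196900; adjusted p = 0.0150) and 5.75 ± 0.98 (Csa2G193340; adjusted p = 0.00887). Copper transporter 1 (Cucumis_sativus_newGene_1137) and acetylornithine deacetylase (Csa3G902920) rose by 8.31 ± 1.44 and 5.47 ± 0.98. The copper transporter was highest in replicate 1 of the double mutant, at 54.8 CPM. Leaving out 1 library moved some folds by over 1.5 times, to log2 values of 6.80 ± 1.23 for copper transporter 1 without Csspt Csalc replicate 1, 4.88 ± 0.99 for acetylornithine deacetylase without Csspt Csalc replicate 1, 6.33 ± 1.20 for acetylornithine deacetylase without WT replicate 2, 4.98 ± 1.47 for Csa2G028480 without WT replicate 1 (adjusted p = 0.119), 6.58 ± 1.77 for Csa2G028480 without WT replicate 3 (adjusted p = 0.0937) and 6.36 ± 1.24 for Csa2G193340 without WT replicate 1. The copper transporter kept 2 WT counts without WT replicate 1, where its fitted log2 fold change, 9.38 ± 1.94, depends on the prior count. Glucan endo-1,3-beta-glucosidase 13 (Csa1G537410) had 1 count in WT and 424 in the double mutant, a ratio of 366 (65.3 to 14491, exact 95% binomial interval for counting error only).

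The falls in the double mutant included pectate lyase 5 (Csa2G350210), which went from 58.4 ± 9.52 CPM in WT to 1.74 ± 0.314 (log2 fold change -5.06 ± 0.66, adjusted p = 0.00239). NAC56 (Csa3G100800) fell from 159.8 ± 8.54 to 4.78 ± 1.56 CPM, PIN2 (Csa1G427480) with a log2 fold change of -4.74 ± 0.57, and the GDSL lipase Csa6G518310 from 74.1 ± 6.86 to 2.14 ± 0.617. In Csspt, NAC56 had 31.7, 39.8 and 46.0 CPM, PIN2 had 4.99, 4.60 and 6.47, and the GDSL lipase had 55.8, 53.5 and 55.9. NAC56 and PIN2 were thus well below WT in Csspt as well, though not called there with 12 libraries. CYP71AN24 (Cucumis_sativus_newGene_1864), an Ole e 6-like protein (Csa5G222980), FAF3 (Csa7G389490) and thionin-like protein 2 (Csa7G446640) had log2 fold changes of -5.30 ± 0.61, -6.31 ± 1.02, -5.12 ± 0.93 and -4.78 ± 0.90. A 21 kDa protein (Csa3G176250) had 226 counts in WT and 0 in the double mutant, at least 87.3-fold lower over the same floor. The remodeler SYD (Csa6G305300) had 435 and 3 counts, a ratio of 168 (57.1 to 818), and it was at 4.48 ± 3.85 CPM in WT, with 0.0953 in replicate 2. Its call ended without replicate 1 of the double mutant (adjusted p = 0.122) and held without WT replicate 2 (adjusted p = 0.0287). The log2 fold change went from -7.22 to -10.3 ± 2.96 and -7.80 ± 1.44. The former had 0 counts left in the double mutant, so its size depends on the prior count. FAF3 moved to -5.73 ± 1.16 without Csspt Csalc replicate 3.

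**Figure D2:**
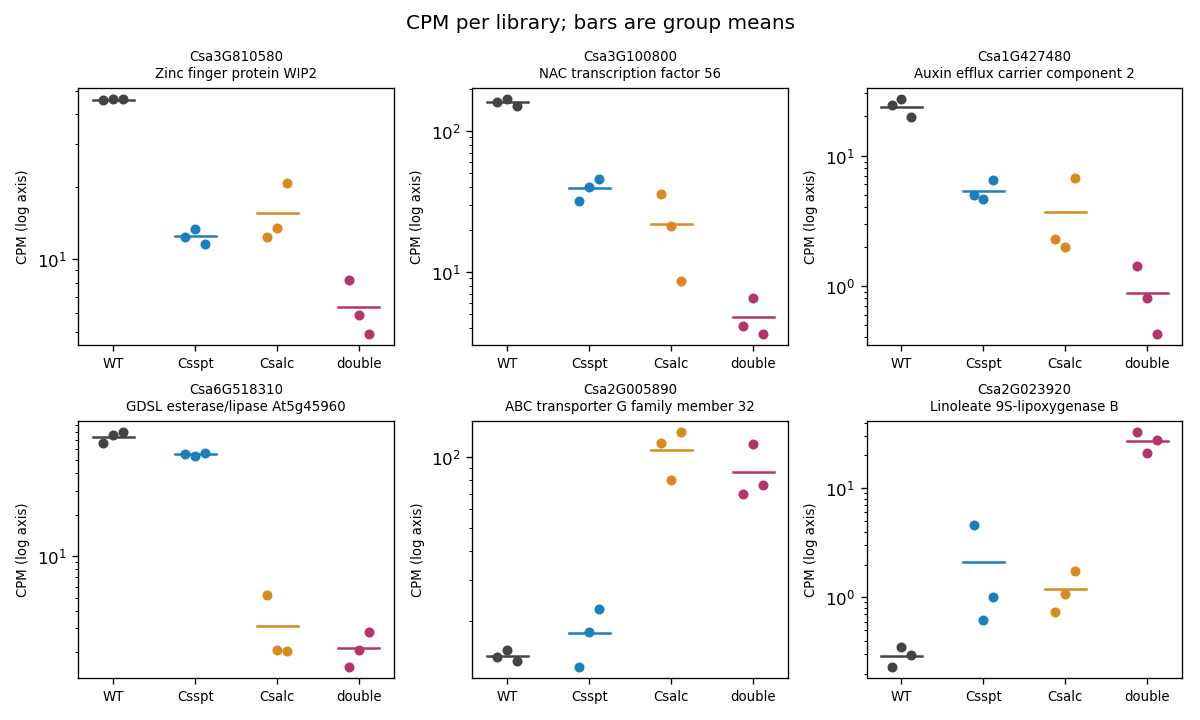
CPM on a log axis in each library (points) with group means (bars) for 6 genes named by the fixed rule, in WT, Csspt, Csalc and the double mutant, with 3 libraries per group. NAC56 has group means of 159.8, 39.2, 21.9 and 4.78 CPM in that order.

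In the double mutant 711 genes rose and 642 fell among 18850 tested (edgeR, adjusted p under 0.05), while without Csalc replicate 3, 3668 rose and 3207 fell among 19060. All 1353 calls of the 12-library fit were also called in the same direction without Csalc replicate 3. Both fits use the same WT and double mutant libraries, so this is no independent check of the calls. The count was 433 without WT replicate 1, 502 without WT replicate 2, 451 without WT replicate 3, and 535, 585 and 699 without replicates 1, 2 and 3 of the double mutant. Falling genes were enriched for auxin-activated signaling (11 of 64 members against 2.24 by chance, adjusted p = 0.0122) and plant hormone signal transduction (33 of 456 members against 15.6 by chance, adjusted p = 0.00328), by a one-sided Fisher exact test. Rising genes were enriched for linoleic acid metabolism (8 of 25 members against 1.27 by chance, adjusted p = 0.00256), starch and sucrose metabolism (26 of 231 members against 11.8 by chance, adjusted p = 0.00632) and chlorophyll biosynthesis (5 of 14 members against 0.563 by chance, adjusted p = 0.0391). Without Csalc replicate 3, 45 GO terms passed among rising genes and 12 among falling genes, against 5 and 1 with it. KEGG terms numbered 10 and 5, against 3 and 1. Chlorophyll biosynthesis was not among them. The lowest p belonged to structural constituent of ribosome (154 of 307 members against 63.2 by chance, adjusted p = 2.74e-28). Photosystem II (18 of 24 members against 4.94 by chance, adjusted p = 3.20e-06) and the proteasome core complex (14 of 18 members against 3.70 by chance, adjusted p = 3.57e-05) also passed.

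Of 26 tested carpel and transmitting tract regulators, 2 rose and 3 fell (2 and 4 adjusted over the list alone, 3 and 6 of 27 without Csalc replicate 3, median log2 fold change -0.08, camera adjusted p = 0.447). WIP2 (Csa3G810580), BEE 3 (Csa1G024150) and auxin response factor 3 (Csa6G518210) fell, at -2.86 ± 0.24, -2.04 ± 0.26 and -0.72 ± 0.18, and an AGAMOUS gene (Csa1G467100) and YABBY 2 (Csa6G426940) rose, at 2.14 ± 0.26 and 0.78 ± 0.17. Of 115 tested auxin genes, 2 rose and 16 fell (3 and 24 adjusted over the list alone, 16 and 40 of 120 without Csalc replicate 3, median log2 fold change -0.25, camera adjusted p = 0.00332, or 0.463 with an estimated correlation). IAA29 (Csa1G231530) and SAUR40 (Csa3G883020) fell, at -2.22 ± 0.43 and -2.08 ± 0.44. Of 22 tested gibberellin genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone, 4 and 3 of 23 without Csalc replicate 3, median log2 fold change 0.33, camera adjusted p = 0.575). Of 53 tested cytokinin genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone, 8 and 8 of 54 without Csalc replicate 3, median log2 fold change 0.08, camera adjusted p = 0.864). Of 104 tested ethylene genes, 7 rose and 2 fell (7 and 4 adjusted over the list alone, 26 and 20 of 107 without Csalc replicate 3, median log2 fold change 0.32, camera adjusted p = 0.493). Of 39 tested abscisic acid genes, 5 rose and 4 fell (11 and 5 adjusted over the list alone, 12 and 8 of 39 without Csalc replicate 3, median log2 fold change -0.06, camera adjusted p = 0.932). Of 18 tested brassinosteroid genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone, 0 and 1 of 18 without Csalc replicate 3, median log2 fold change -0.16, camera adjusted p = 0.565). Of 44 tested jasmonate genes, 8 rose and 0 fell (13 and 1 adjusted over the list alone, 19 and 4 of 45 without Csalc replicate 3, median log2 fold change 0.58, camera adjusted p = 0.00807, or 0.463 with an estimated correlation). Its 9-lipoxygenase members act in a branch of oxylipin synthesis other than that of jasmonate.

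Of 115 tested pectin-modifying enzymes, 5 rose and 6 fell (10 and 12 adjusted over the list alone, 29 and 27 of 116 without Csalc replicate 3, median log2 fold change 0.06, camera adjusted p = 0.743). Rhamnogalacturonate lyase B (Csa3G892760) fell, at -3.89 ± 0.27, and polygalacturonase Csa3G838140 rose, at 3.26 ± 0.61, or 2.66 ± 0.58 without Csspt Csalc replicate 1. Among wall-loosening and wall-hydrolysing enzymes, 16 rose, 8 fell and 99 were not called (21 and 9 adjusted over the list alone, 44 and 14 of 125 without Csalc replicate 3, median log2 fold change 0.51, camera adjusted p = 0.00846, or 0.650 with an estimated correlation). Beta-galactosidase 3 (Csa2G249880) fell, at -4.23 ± 0.49, while xyloglucan endotransglucosylase 10 (Csa4G000010) rose, at 3.75 ± 0.67. Of 73 tested arabinogalactan proteins and other wall glycoproteins, 6 rose and 2 fell (10 and 6 adjusted over the list alone, 23 and 12 of 74 without Csalc replicate 3, median log2 fold change 0.26, camera adjusted p = 0.493). Of 48 tested secreted pistil proteins, 7 rose and 2 fell (8 and 4 adjusted over the list alone, 15 and 5 of 49 without Csalc replicate 3, median log2 fold change 0.50, camera adjusted p = 0.136). STIG1-like protein 1 (Csa1G059710), a stigma protein, fell, at -4.39 ± 0.82, or -5.11 ± 0.99 without Csspt Csalc replicate 2, and the lipid-transfer protein DIR1 (Csa7G372360) rose, at 5.37 ± 0.66. Of 31 tested pollen tube reception and guidance receptors, 3 rose and 1 fell (6 and 4 adjusted over the list alone, 12 and 5 of 32 without Csalc replicate 3, median log2 fold change 0.45, camera adjusted p = 0.261). FERONIA (Csa4G129580) and HERK 1 (Csa5G177140), receptor kinases, rose, at 1.58 ± 0.28 and 1.52 ± 0.26. Of 107 tested cuticle and surface lipid genes, 11 rose and 9 fell (17 and 9 adjusted over the list alone, 26 and 18 of 110 without Csalc replicate 3, median log2 fold change 0.29, camera adjusted p = 0.447). Of 142 tested phenylpropanoid and lignin genes, 11 rose and 0 fell (13 and 2 adjusted over the list alone, 59 and 10 of 144 without Csalc replicate 3, median log2 fold change 0.60, camera adjusted p = 0.00332, or 0.463 with an estimated correlation). Of 24 tested flavonoid genes, 3 rose and 4 fell (3 and 4 adjusted over the list alone, 10 and 5 of 25 without Csalc replicate 3, median log2 fold change 0.32, camera adjusted p = 0.493).

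Of 53 tested photosynthesis genes, 9 rose and 0 fell (11 and 0 adjusted over the list alone, 38 and 3 of 54 without Csalc replicate 3, median log2 fold change 0.82, camera adjusted p = 4.64e-04, or 0.650 with an estimated correlation). Chlorophyll a-b binding protein 3 (Csa1G445860) and plastocyanin (Csa3G875430) rose, at 2.77 ± 0.54 and 2.02 ± 0.45. Of 174 tested defence proteins, 14 rose and 7 fell (29 and 10 adjusted over the list alone, 67 and 21 of 182 without Csalc replicate 3, median log2 fold change 0.50, camera adjusted p = 0.00927, or 0.650 with an estimated correlation). Thaumatin-like protein Csa5G604230 rose, at 4.24 ± 0.90. Of 283 tested ribosomal proteins, 5 rose and 1 fell (0 and 0 adjusted over the list alone, 151 and 3 of 283 without Csalc replicate 3, median log2 fold change 0.35, camera adjusted p = 1.79e-10, or 0.650 with an estimated correlation). Of 32 tested core histones, 0 rose and 5 fell (0 and 8 adjusted over the list alone, 4 and 11 of 32 without Csalc replicate 3, median log2 fold change -0.22, camera adjusted p = 0.00927, or 0.726 with an estimated correlation). Of 152 tested cell cycle genes, 5 rose and 5 fell (8 and 6 adjusted over the list alone, 43 and 23 of 153 without Csalc replicate 3, median log2 fold change 0.37, camera adjusted p = 0.150). Of 66 tested heat shock proteins, 3 rose and 1 fell (3 and 1 adjusted over the list alone, 8 and 11 of 66 without Csalc replicate 3, median log2 fold change 0.00, camera adjusted p = 0.911). Of 156 tested redox genes, 17 rose and 5 fell (21 and 6 adjusted over the list alone, 41 and 20 of 159 without Csalc replicate 3, median log2 fold change 0.12, camera adjusted p = 0.184). Respiratory burst oxidase A (Csa4G050170) rose, at 3.80 ± 0.77. Of 76 tested sugar genes, 4 rose and 5 fell (6 and 7 adjusted over the list alone, 12 and 17 of 78 without Csalc replicate 3, median log2 fold change -0.05, camera adjusted p = 0.493). Polyol transporter 5 genes Csa7G257340 and Csa3G095020 fell, at -2.42 ± 0.29 and -2.19 ± 0.21. Of 21 tested terpene genes, 3 rose and 0 fell (4 and 2 adjusted over the list alone, 5 and 2 of 21 without Csalc replicate 3, median log2 fold change 0.29, camera adjusted p = 0.192). Of 118 tested cell death and senescence genes, 6 rose and 6 fell (8 and 7 adjusted over the list alone, 24 and 26 of 120 without Csalc replicate 3, median log2 fold change 0.07, camera adjusted p = 0.743).

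Marker lists of other cell types were read in the same way. Of 45 tested vascular markers, 6 rose and 1 fell (8 and 1 adjusted over the list alone, 17 and 5 of 46 without Csalc replicate 3, median log2 fold change 0.56, camera adjusted p = 0.0255, or 0.463 with an estimated correlation). Without Csalc replicate 3 the vascular list had camera adjusted p = 0.0885, the upper end of a range from 0.00590 over the libraries left out. Cellulose synthase A subunits 7 (Csa2G070320) and 8 (Csa1G470270), of the secondary wall, rose, at 3.16 ± 0.68 and 2.68 ± 0.67. Of 15 tested pollen markers, 0 rose and 1 fell (0 and 2 adjusted over the list alone, 1 and 3 of 16 without Csalc replicate 3, median log2 fold change -0.17, camera adjusted p = 0.221). Of 44 tested ovule and seed markers, 7 rose and 1 fell (7 and 1 adjusted over the list alone, 10 and 7 of 45 without Csalc replicate 3, median log2 fold change 0.16, camera adjusted p = 0.493). Of 56 tested trichome and epidermis markers, 5 rose and 3 fell (6 and 3 adjusted over the list alone, 18 and 9 of 56 without Csalc replicate 3, median log2 fold change 0.21, camera adjusted p = 0.261). Of 12 tested petal, stamen and nectary markers, 0 rose and 3 fell (0 and 3 adjusted over the list alone, 1 and 6 of 13 without Csalc replicate 3, median log2 fold change -0.20, camera adjusted p = 0.130). Carotenoid cleavage dioxygenase 1 (Csa7G428120) fell, at -1.59 ± 0.19. The median and the camera direction had opposite signs for the pectin, abscisic acid and heat shock lists, none of which was called. Under the other scalings (FPKM as deposited, shifted by the median, by TMM factors or by quantiles, and counts by DESeq2 size factors) the medians of the 9 called lists kept their sign. The carpel regulator, pectin, gibberellin, cytokinin, abscisic acid, cell cycle, heat shock, cuticle, cell death, sugar, ovule and trichome lists changed sign under at least 1 of them. With members at 0 counts set to their bound, the jasmonate and phenylpropanoid medians were 0.58 and 0.60.

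**Figure D3:**
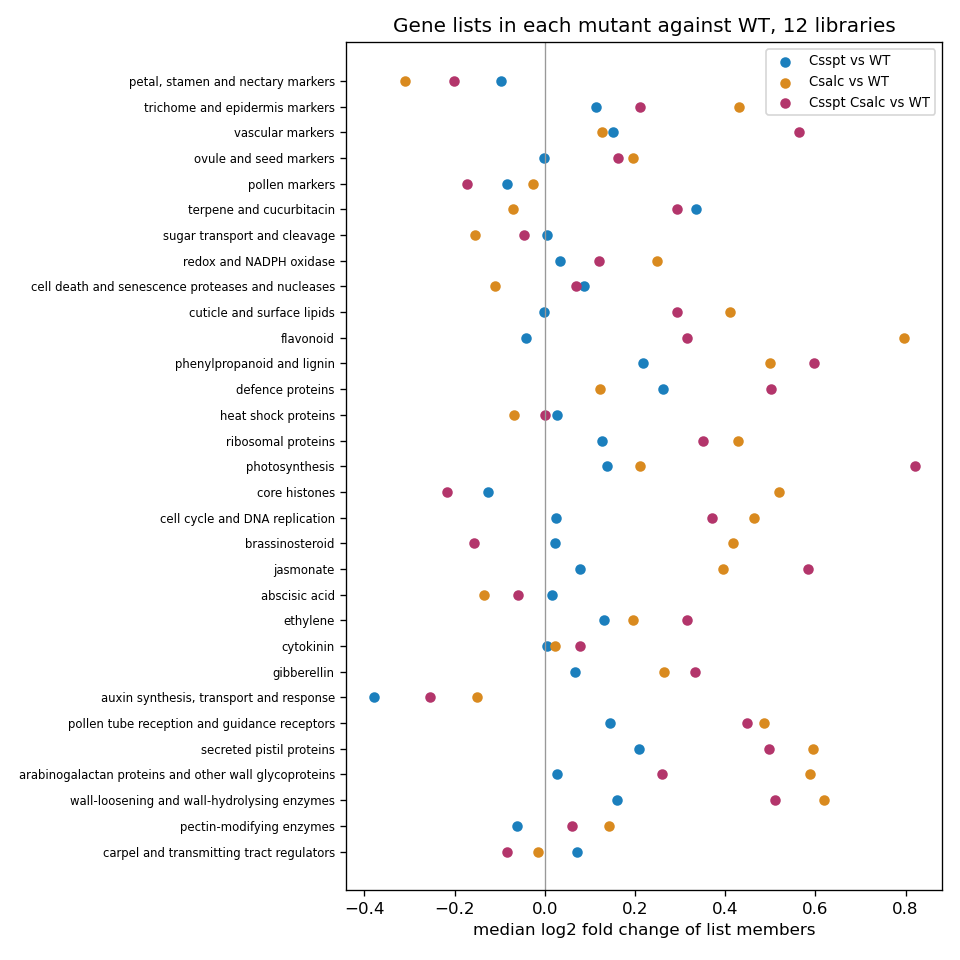
Median log2 fold change of the members of each fixed gene list (rows) in Csspt, Csalc and the double mutant against WT, from the 12-library fit; points carry no error bars. The photosynthesis median is 0.82 in the double mutant and 0.14 in Csspt.

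Against Csspt, the double mutant had lower GDSL lipase Csa6G518310 (-4.68 ± 0.38, adjusted p = 0.00154), beta-galactosidase 3 (Csa2G249880; -3.37 ± 0.47), CYP71AN24 (Cucumis_sativus_newGene_1864; -3.27 ± 0.55), NAC56 (Csa3G100800; -3.03 ± 0.44) and LIGHT-DEPENDENT SHORT HYPOCOTYLS 4 (Csa3G383780), which went from 16.6 ± 1.09 to 1.74 ± 0.474 CPM. Lipoxygenase A (Csa2G023910) was at least 558-fold higher, and HVA22-like protein f (Csa6G423340), DIR1 (Csa7G372360), threonine dehydratase (Csa6G448730) and PCC13-62 (Csa6G324880) rose by 3.58 ± 0.48, 3.50 ± 0.59, 2.53 ± 0.41 and 2.46 ± 0.38. Single libraries moved 2 of these folds by over 1.5 times, to log2 values of -2.69 ± 0.50 for CYP71AN24 without Csspt replicate 1 and 4.17 ± 0.48 for HVA22-like protein f without Csspt replicate 1. In this comparison 22 genes rose and 46 fell among 18850 tested (edgeR, adjusted p under 0.05), while without Csalc replicate 3, 1491 rose and 1257 fell among 19060. By camera, the lists with adjusted p under 0.05 were, upward, wall-loosening enzymes (median 0.22, 0.00645), jasmonate genes (median 0.22, 0.00645), cell cycle genes (median 0.15, 0.0239), photosynthesis genes (median 0.64, 5.46e-07), ribosomal proteins (median 0.21, 9.97e-09), phenylpropanoid genes (median 0.43, 6.15e-04), vascular markers (median 0.16, 0.0345). Downward, they were core histones (median -0.26, 0.0185). With an estimated correlation the lowest adjusted p among these was 0.588. Leaving out Csalc replicate 3 ended the camera call (adjusted p then in brackets) of core histones (0.0590) and vascular markers (0.0807).

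Against Csalc, beta-galactosidase 3 (Csa2G249880), LIGHT-DEPENDENT SHORT HYPOCOTYLS 4 (Csa3G383780), the exchange factor GNL2 (Csa2G004740), an aquaporin (Csa3G345890) and phylloplanin (Csa3G159420) were lower in the double mutant, at -3.71 ± 0.47, -3.44 ± 0.21, -3.60 ± 0.45, -4.89 ± 0.85 and -2.42 ± 0.40. Lipoxygenase A (Csa2G023910) was at least 601-fold higher, and lipoxygenases Csa2G023920 and Csa2G023900, feruloyl CoA ortho-hydroxylase 1 (Csa3G821020) and HVA22-like protein f (Csa6G423340) rose by 4.51 ± 0.69, 4.10 ± 0.74, 4.42 ± 0.65 and 4.07 ± 0.49. Without Csalc replicate 3, GNL2 and Csa2G023900 had log2 fold changes of -2.86 ± 0.23 and 4.84 ± 0.75. The log2 fold change of feruloyl CoA ortho-hydroxylase 1 went from 4.42 ± 0.65 to 5.04 ± 0.76 without Csalc replicate 2. The call of the aquaporin ended without Csspt Csalc replicate 2 (adjusted p = 0.0914). In this comparison 87 genes rose and 47 fell among 18850 tested (edgeR, adjusted p under 0.05), while without Csalc replicate 3, 1190 rose and 941 fell among 19060. By camera, the lists with adjusted p under 0.05 were, upward, jasmonate genes (median 0.21, 0.00129), photosynthesis genes (median 0.63, 1.10e-07), defence proteins (median 0.24, 5.54e-05), phenylpropanoid genes (median 0.22, 9.91e-05), terpene genes (median 0.55, 4.90e-04), vascular markers (median 0.14, 4.90e-04). Downward, they were core histones (median -0.94, 2.04e-07). With an estimated correlation the lowest adjusted p among these was 0.463. Leaving out Csalc replicate 3 ended the camera call (adjusted p then in brackets) of core histones (0.193), defence proteins (0.319) and terpene genes (0.403). Its omission brought under the threshold wall-loosening enzymes (0.00532, upward, or 0.624 with an estimated correlation), ribosomal proteins (1.12e-05, upward, or 0.624 with an estimated correlation) and petal, stamen and nectary markers (0.0402, downward, or 0.624 with an estimated correlation).

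Between the single mutants, GDSL lipase Csa6G518310 (4.15 ± 0.37, adjusted p = 0.00382), U-box protein 51 (Csa6G363600; 2.29 ± 0.19), lysine histidine transporter 1 (Csa5G590140; 1.78 ± 0.21), aldehyde dehydrogenase 3F1 (Csa4G291370; 1.77 ± 0.24) and mannitol dehydrogenase (Csa2G299950; 1.65 ± 0.24) were higher in Csspt than in Csalc. ABC transporter G32 (Csa2G005890), JASON (Csa4G063990), CER3 (Csa1G294020) and 3-ketoacyl-CoA synthase 10 (Csa4G649640) were lower in Csspt, at -2.60 ± 0.26, -1.84 ± 0.19, -1.75 ± 0.23 and -1.61 ± 0.22. In this comparison 8 genes rose and 4 fell among 18850 tested (edgeR, adjusted p under 0.05), while without Csalc replicate 3, 48 rose and 47 fell among 19060. By camera, the lists with adjusted p under 0.05 were, upward, defence proteins (median 0.12, 0.0331), cell death genes (median 0.17, 0.0108), terpene genes (median 0.88, 0.00760). Downward, they were wall glycoproteins (median -0.54, 0.0317), cell cycle genes (median -0.38, 9.55e-05), core histones (median -0.63, 0.0142), ribosomal proteins (median -0.30, 8.18e-15), cuticle genes (median -0.30, 0.0454). With an estimated correlation the lowest adjusted p among these was 0.686. Leaving out Csalc replicate 3 ended the camera call (adjusted p then in brackets) of wall glycoproteins (0.705), core histones (0.701, in the opposite direction), ribosomal proteins (0.0912), defence proteins (0.539, in the opposite direction), cuticle genes (0.322) and terpene genes (0.188). Its omission brought under the threshold photosynthesis genes (8.11e-08, downward, or 0.614 with an estimated correlation). In Csalc replicate 3, core histones differed from replicates 1 and 2 by a median of 1.37 and terpene genes by -2.80 on the log2 scale. The interaction, which asks whether the double mutant departs from the sum of the single mutants on the log2 scale, called 0 genes by edgeR. Another 2 tools gave 2 calls (limma on log2 FPKM) and 62 (DESeq2), and without Csalc replicate 3 edgeR called 5. By edgeR, 1274 genes had an unadjusted p under 0.05, where chance alone would give 942.5.

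Of the 11 genes called in Csspt, 11 were called in the same direction in the double mutant, as were 132 of the 148 called in Csalc, and 9 genes were shared by both single mutants. Independent lists would share 0.341, 4.02 and 0.0626 falling genes, where 10, 109 and 9 were found, and 0.0377, 1.13 and 0.00159 rising genes, where 1, 23 and 0 were found. Across genes, which are not independent replicates, fold changes correlated at r = 0.672, 0.660 and 0.508, with covariances of 0.378, 0.595 and 0.269. In 20 simulations of unchanged groups that shared simulated WT libraries, r averaged 0.5001, 0.504 and 0.501 (highest 0.524, 0.532 and 0.531), so with 12 libraries the r of Csspt and Csalc lay within the simulated range. With the 11 other than Csalc replicate 3, r was 0.664, 0.548 and 0.560, against simulated means of 0.501, 0.442 and 0.440 (highest 0.560, 0.4998 and 0.483), above the simulated range for each pair. This baseline was chosen after the data were seen. With 12 libraries the simulated covariance averaged 0.139, 0.139 and 0.139 (highest 0.149, 0.150 and 0.151), below the covariance found for each pair. At most 0 genes were shared in those simulations. No gene was changed in them, so few calls could arise, and this count is no baseline for the overlaps found. Their WT libraries were drawn at the spread of the whole fit, which includes that of Csalc replicate 3. Without Csalc replicate 3 the covariances were 0.423, 0.395 and 0.248, against simulated means of 0.0735, 0.0744 and 0.0739. With 3 WT libraries the controls could not be split into parts of at least 2 libraries, so part of the excess may come from the shared controls. Without Csalc replicate 3, 798, 740 and 317 genes were shared.

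The authors' deposited table gave 220 regulated genes for Csspt against WT, 271 for Csalc and 2059 for the double mutant, at an FDR under 0.05 and a fold of at least 2. It gave 2507, 424 and 6975 at any fold. Of the 12-library edgeR calls, 10 of 11, 112 of 148 and 837 of 1353 were regulated in the same direction in the authors' deposited table at that fold. The edgeR calls carry no fold threshold, and 920 of those in the double mutant were at least 2-fold.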

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

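The interaction of the mutations, tested across gene lists with camera, passed for 6 lists at the preset correlation of 0.01, which asks whether the effect of one mutation differs with and without the other. The adjusted p was 1.13e-05 for photosynthesis (median 0.46 on the log2 scale), 3.91e-04 for core histones (median -0.77), 3.91e-04 for ribosomal proteins (median -0.20), 0.00576 for auxin genes (median 0.11), 0.0163 for phenylpropanoid and lignin genes (median 0.08) and 0.0392 for vascular markers (median 0.22). With an estimated correlation no list passed, and the lowest adjusted p among the 6 was 0.829. Csalc replicate 3 enters this contrast. Leaving out Csalc replicate 3 ended the camera call (adjusted p then in brackets) of core histones (0.606), ribosomal proteins (0.341, in the opposite direction), phenylpropanoid genes (0.336) and vascular markers (0.1004). Its omission brought under the threshold pectin-modifying enzymes (0.00604, upward, or 0.609 with an estimated correlation) and wall-loosening enzymes (0.0283, upward, or 0.609 with an estimated correlation).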

How the results depend on the processing

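Tests added after the data were seen are the fits on the 11 libraries other than Csalc replicate 3 with DESeq2, a replicate block or an estimated correlation, the annotation terms of that fit, the fold changes of named genes with each library of the compared groups left out, and the list medians under other scalings. Counts of called genes depended on the tool, the scaling, the filter, the model and the libraries used. With all 12 libraries edgeR called 11 (Csspt), 148 (Csalc), 1353 (the double mutant), 68 (double against Csspt), 134 (double against Csalc), 12 (Csspt against Csalc), 0 (the interaction). Csalc replicate 3 enters the contrasts without Csalc only through the shared spread, the filter and the scaling. Leaving it out took the edgeR calls to 900 in Csspt and 6875 in the double mutant. The common biological coefficient of variation went from 0.363 to 0.193, so its spread held down the 12-library counts there. Counts over 1.5 times apart from the 12-library edgeR counts were as follows, and beyond that library the cause was not tested. 28 (Csspt), 166 (double against Csspt), 302 (double against Csalc), 21 (Csspt against Csalc), 2 (the interaction) with limma on log2 FPKM. 6 (Csspt), 232 (double against Csalc), 19 (Csspt against Csalc), 2 (the interaction) with limma on log2 FPKM, pseudocount 0.1. 20 (Csspt), 132 (double against Csspt), 278 (double against Csalc), 20 (Csspt against Csalc), 2 (the interaction) with limma on log2 FPKM, pseudocount 0.5. 18 (Csspt), 197 (double against Csspt), 352 (double against Csalc), 3 (the interaction) with limma on log2 FPKM, no filter. 29 (Csspt), 211 (double against Csspt), 320 (double against Csalc), 22 (Csspt against Csalc), 1 (the interaction) with limma on log2 FPKM, median shift. 26 (Csspt), 170 (double against Csspt), 303 (double against Csalc), 24 (Csspt against Csalc), 2 (the interaction) with limma on log2 FPKM, TMM factors. 33 (Csspt), 229 (double against Csspt), 303 (double against Csalc), 24 (Csspt against Csalc), 2 (the interaction) with limma on log2 FPKM, quantile. 29 (Csspt), 189 (double against Csspt), 320 (double against Csalc), 22 (Csspt against Csalc), 2 (the interaction) with limma on log2 FPKM, no trend. 3810 (Csspt), 882 (Csalc), 7575 (the double mutant), 4595 (double against Csspt), 1692 (double against Csalc), 261 (Csspt against Csalc), 396 (the interaction) with limma on log2 FPKM, library weights. 1219 (Csspt), 2 (Csalc), 6638 (the double mutant), 1645 (double against Csspt), 0 (double against Csalc), 0 (Csspt against Csalc) with edgeR, fit of the compared groups. 3 (Csspt), 75 (Csalc), 33 (double against Csspt), 16 (double against Csalc), 2 (Csspt against Csalc) with edgeR, replicate block. 4 (Csspt) with edgeR, no filter. 321 (Csspt), 1595 (Csalc), 2940 (the double mutant), 872 (double against Csspt), 966 (double against Csalc), 419 (Csspt against Csalc), 62 (the interaction) with DESeq2. 2125 (Csspt), 1670 (Csalc), 7627 (the double mutant), 3967 (double against Csspt), 3392 (double against Csalc), 757 (Csspt against Csalc), 592 (the interaction) with DESeq2 on the 11 libraries other than Csalc replicate 3. 547 (Csspt), 535 (Csalc), 6379 (the double mutant), 2369 (double against Csspt), 1611 (double against Csalc), 27 (Csspt against Csalc), 1 (the interaction) with edgeR, replicate block, on the 11 libraries other than Csalc replicate 3. 846 (the double mutant), 2 (the interaction) with limma on log2 FPKM, mean FPKM of at least 5. 1 (Csspt against Csalc), 1 (the interaction) with limma on log2 FPKM, replicate block.

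Leaving out each library in turn gave counts of 0 to 900 (genes, Csspt vs WT), 33 to 1271 (genes, Csalc vs WT), 433 to 6875 (genes, Csspt Csalc vs WT), 7 to 2748 (genes, Csspt Csalc vs Csspt), 5 to 2131 (genes, Csspt Csalc vs Csalc), 2 to 95 (genes, Csspt vs Csalc), 0 to 5 (genes, interaction), 0 to 798 (shared calls, Csspt vs WT and Csspt Csalc vs WT), 30 to 740 (shared calls, Csalc vs WT and Csspt Csalc vs WT), 0 to 317 (shared calls, Csspt vs WT and Csalc vs WT), 1 to 4 (lists, Csspt vs WT), 3 to 6 (lists, Csalc vs WT), 5 to 9 (lists, Csspt Csalc vs Csspt), 3 to 9 (lists, Csspt vs Csalc). The highest gene and overlap counts came without Csalc replicate 3, except for Csalc against WT, where they came without Csalc replicate 1 for genes. Adjusted p ranges over left-out libraries were: photosynthesis, Csalc vs WT, 2.10e-07 to 0.994, then defence proteins, Csalc vs WT, 0.00774 to 0.910, then vascular markers, 0.00590 to 0.0885, then ribosomal proteins, Csspt Csalc vs Csalc, 1.12e-05 to 0.686, then core histones, Csspt vs Csalc, 8.86e-05 to 0.701, then photosynthesis, Csspt vs Csalc, 8.11e-08 to 0.820, then defence proteins, Csspt vs Csalc, 0.0107 to 0.539, then ribosomal proteins, interaction, 2.33e-08 to 0.341. Csalc replicate 3 left out gave 1 end of each of these ranges.

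6 (shared calls, Csspt vs WT and Csspt Csalc vs WT), 5 (shared calls, Csspt vs WT and Csalc vs WT) with limma on log2 FPKM, pseudocount 0.1. 4 (shared calls, Csspt vs WT and Csspt Csalc vs WT), 4 (shared calls, Csspt vs WT and Csalc vs WT) with edgeR, no filter. 3 (shared calls, Csspt vs WT and Csspt Csalc vs WT), 69 (shared calls, Csalc vs WT and Csspt Csalc vs WT), 3 (shared calls, Csspt vs WT and Csalc vs WT) with edgeR, replicate block. 0 (lists, Csspt vs WT), 0 (lists, Csalc vs WT), 0 (lists, Csspt Csalc vs WT), 0 (lists, Csspt Csalc vs Csspt), 0 (lists, Csspt Csalc vs Csalc), 0 (lists, Csspt vs Csalc), 0 (lists, interaction) with estimated correlation. 0 (lists, Csspt vs WT), 0 (lists, Csspt Csalc vs Csspt), 1 (lists, Csspt Csalc vs Csalc), 0 (lists, Csspt vs Csalc), 0 (lists, interaction) with fry. 0 (lists, Csspt vs WT), 0 (lists, Csalc vs WT), 0 (lists, Csspt Csalc vs WT), 0 (lists, Csspt Csalc vs Csspt), 0 (lists, Csspt Csalc vs Csalc), 0 (lists, Csspt vs Csalc), 0 (lists, interaction) with estimated correlation on the 11 libraries other than Csalc replicate 3. 5 (lists, Csspt vs Csalc) with camera on log2 FPKM, TMM factors. 1 (GO terms, Csalc vs WT, up), 1 (GO terms, Csalc vs WT, down), 45 (GO terms, Csspt Csalc vs WT, up), 12 (GO terms, Csspt Csalc vs WT, down), 3 (KEGG terms, Csalc vs WT, up), 1 (KEGG terms, Csalc vs WT, down), 10 (KEGG terms, Csspt Csalc vs WT, up), 5 (KEGG terms, Csspt Csalc vs WT, down) with calls of the fit other than Csalc replicate 3.

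Adjusted p of lists in the double mutant, or in the contrast given, that crossed the threshold or turned: 0.650 (wall-loosening and wall-hydrolysing enzymes), 0.463 (auxin synthesis, transport and response), 0.463 (jasmonate), 0.726 (core histones), 0.650 (photosynthesis), 0.650 (ribosomal proteins), 0.650 (defence proteins), 0.463 (phenylpropanoid and lignin), 0.463 (vascular markers) with estimated correlation. 0.146 (wall-loosening and wall-hydrolysing enzymes), 0.0137 (secreted pistil proteins), 0.00891 (pollen tube reception and guidance receptors), 0.346 (core histones), 0.162 (photosynthesis), 0.135 (ribosomal proteins), 0.135 (defence proteins), 0.00891 (redox and NADPH oxidase), 0.0166 (pollen markers), 0.0116 (ovule and seed markers), 0.0126 (petal, stamen and nectary markers) with fry. 0.00895 (secreted pistil proteins), 0.0738 (vascular markers) with camera on log2 FPKM, TMM factors. 0.393 (wall-loosening and wall-hydrolysing enzymes), 0.393 (auxin synthesis, transport and response), 0.588 (jasmonate), 0.742 (core histones), 0.393 (photosynthesis), 0.309 (ribosomal proteins), 0.0640 (defence proteins), 0.309 (phenylpropanoid and lignin), 0.407 (vascular markers), 0.928 (core histones, Csspt vs Csalc, opposite direction), 0.614 (defence proteins, Csspt vs Csalc, opposite direction), 0.806 (ribosomal proteins, interaction, opposite direction) with estimated correlation on the 11 libraries other than Csalc replicate 3.

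Over 50 pairs of a named gene and a mutant, 849 values under alternatives kept the direction in every case: 589 stayed past the threshold and 260 did not. These genes were chosen from the same libraries for large changes without overlap, so the choice itself favours a kept direction. Same-numbered libraries of different groups showed little shared deviation (2 of 18 pairs above r = 0.1, mean -0.0250). Replicate 3 sets much of the deviation of every Csalc library, so this check cannot exclude a pairing of the samples. Whether a call lost with the block marks a weaker effect stays undecided. The table had a single row for each gene, so the alternative of separate rows was not run, and the fit of the compared groups alone does not apply to the interaction. On FPKM, the shift by the median moved the median of all genes in Csalc from 0.12 to -0.03, and in the double mutant from 0.10 to -0.03, where the rising share of calls went from 59.3% to 47.9%. In Csalc that share was 59.6% with DESeq2, 70.7% without Csalc replicate 1 and 41.2% without Csalc replicate 3. Depth limits genes near the floor of 3 counts.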

Other observations

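Outside the lists fixed in advance, the genes that set Csalc replicate 3 apart were described by name after their values were seen. Alpha-farnesene synthase (Csa3G095040) had 1981 and 1366 CPM in replicates 1 and 2 and 3.12 in replicate 3, and phenylalanine ammonia-lyase 1 (Csa6G445240) 1119, 1238 and 2.38. DRT100 (Csa3G697970) and EXORDIUM-like 5 (Csa6G118330) went the other way, with 255 and 327 CPM in replicate 3 and at most 1.57 and 4.24 in the others.

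The tests of mixture, swap, vascular tissue, the shift along the axis of Csalc replicate 3 and the single double mutant library were chosen after the result was seen. The bounds for the evening clock genes were set before their values were viewed, except that of Adagio protein 3 (Csa5G021300, log2 difference 1.68). They were set after the values had been computed and after LHY and other morning genes had been seen. For the distance of Csalc replicate 3, a partial mixture was argued against: 72 of 2134 genes of at least 100 CPM in both other Csalc libraries lay under 5% of their mean there. A swap with another library of the series was argued against too, since 0 of the other 11 libraries lay closest to a library of another group; a swap with a sample from outside stays open. Harvest at another time of day stays open. The 13 evening clock genes differed by a median of 0.76 on the log2 scale (SE 0.48), with 9 higher. That median lay between the bounds of above 1 and at most 0 set beforehand, while the 7 morning genes had a median of -1.25. This SE, and those of the marker lists below, are of means over genes, and they do not cover the spread between libraries. No biological explanation was tested, since the genotype is shared with replicates 1 and 2.

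For the higher vascular markers of the double mutant, the single library Csspt Csalc replicate 1 was argued against as the whole cause: without it the median log2 fold change was 0.41, against 0.56 with it. A larger share of vascular tissue may contribute: xylem and phloem markers had medians of 0.90 and 0.62, 0.28 apart (SE 0.55), too wide to exclude a gap. The most abundant of the 45 markers in WT were F-box protein PP2-A11 (Csa3G043900), F-box protein PP2-A14 (Csa5G173520) and PHLOEM PROTEIN 2-LIKE A9 (Csa6G538620), at 284, 149.5 and 120 CPM. They had log2 fold changes of -0.74 ± 0.30, -0.39 ± 0.49 and -0.19 ± 0.23, so they did not move with the list, although a high baseline would hide a small share. They are in the list by name, and whether the F-box proteins mark phloem here was not tested. A shift along the axis of Csalc replicate 3 may contribute as well: there the markers differed from the other Csalc libraries by a median of 0.51 (SE 0.31), within its SE of the bound of 0.5. The genotype effect itself stays among the open explanations, and the list's call is lost with an estimated correlation (adjusted p = 0.463).

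Other splits of the same libraries bear only weakly on chance. For each pairwise comparison the 6 libraries make 10 splits, too few for a share under 0.05. A wrong split also places any real difference inside its groups as spread. That lowers its gene count, so low counts from other splits are no measure of chance. Gene counts as large as the real one came from 1 split for Csspt (real 11, highest other 1), 1 split for Csalc (real 148, highest other 0), 1 split for the double mutant (real 1353, highest other 0), 1 split for double against Csspt (real 68, highest other 0), 1 split for double against Csalc (real 134, highest other 1), 1 split for Csspt against Csalc (real 12, highest other 7), the real split included. Counts of called lists as large came from 8 for Csspt (real 2, highest other 5), 10 for Csalc (real 3, highest other 14), 2 for the double mutant (real 9, highest other 9), 3 for double against Csspt (real 8, highest other 9), 6 for double against Csalc (real 7, highest other 10), 5 for Csspt against Csalc (real 8, highest other 11). For the interaction, the real gene count was 0, so 60 of 60 regroupings gave as many whatever the data, which decides nothing (highest other 552, from a single regrouping; such a count points to a structure of the samples, whose source was not tested). As many lists came from 30 of 60 regroupings (real 6, highest other 11), so chance is not excluded for the lists.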
